A study of Aurantimicrobium photophilum with 8 samples.

How the data were processed

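RNA was taken from 8 cultures of Aurantimicrobium sp. strain MWH-Mo1, 4 kept in constant light and 4 in constant darkness, each of 50 mL in NSY medium at 6 g per litre, collected late in exponential growth and kept in RNAlater. Per the labels' protocols, ribosomal RNA was depleted, libraries were made with a stranded Illumina TruSeq kit, and fragments under 500 bp were selected. Groups and replicate numbers come from the sample titles. The design also names a second species, Rhodoluna lacicola, which was not analysed here.

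The authors deposited 1 table of FPKM values per library, in the layout of a Cufflinks gene tracking table per the file headers, with a lower and an upper confidence bound in FPKM for each feature. Per the submitters' processing notes, Trim Galore 0.4.1, cutadapt 1.12, FastQC, TopHat, Cufflinks and Cuffdiff were used. Their settings, the role of each, the annotation, the genome build beyond the sequence name mo1genome and whether fragments were assigned by strand are not given in the sources used here. All 1792 features were marked OK in every library, and 5 were listed at 0 in at least 1 library. The deposited FPKM summed to between 2.47e+06 and 2.66e+06 per library.

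FPKM depends on the total of mapped fragments, so libraries were rescaled by the median ratio of each feature to its geometric mean over libraries (factors 0.965 to 1.02). Values were tested as log2(rescaled FPKM + 1), on which a fold change understates the change of weakly expressed features. Features with a mean under 1 FPKM were to be left out, and none was. The test was limma's linear model with moderated variances and a mean-variance trend (lmFit and eBayes), light minus dark, 2-sided, with all 8 libraries and no covariates, Benjamini-Hochberg adjustment over 1792 features and a threshold of 0.05. Level differences of at least 1 on the log2 scale were counted as 2-fold. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used for tests, and Python 3.11.15 with matplotlib 3.10.9 for plots.

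Fragment counts were estimated from the listed bounds, taking the upper bound as 2 standard deviations of counting error above the value. Of 1046 estimates under 300 fragments, 44.9% lay within 0.1 of a whole number, where chance gives 20%, so these are estimates and not counts, and no count model was the main test. By this estimate light replicates 3 and 4 and dark replicate 3 were 1.19 to 1.24 times as deep as light replicate 1 and the other libraries 1.00 to 1.12 times. The estimates assume that bounds cover counting error only, which need not hold for features that overlap a neighbour. The overlapping feature at 319632 to 320705 (1074 bases, 4430 FPKM in light and 2009 in darkness) had an estimated 17800 fragments over 8 libraries. The one at 1001571 to 1002860 (1290 bases, 590 and 535 FPKM), which overlaps none, had 83552. Estimates for overlapping features can thus be too low, which also limits limma voom on them.

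The test, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 10 features with the largest rise and the 10 with the largest fall among those past the threshold whose 4 light libraries all lay on one side of the 4 dark ones, together with adjacent features described as a run. It also named members of fixed gene lists. The tables pair no names or products with locus tags, and no reference annotation was used, so the 26 fixed lists could not be matched to features and neither they nor the parts of the rule that rest on them were run. For the same reason at most 2 tags that rose and 2 that fell are printed. Runs of at least 6 adjacent features past the threshold in the same direction, and 90 blocks of consecutive features (89 of 20 and a last one of 12) tested with camera and fry, were chosen after the data were examined in place of the lists. The 5 rising and 5 falling regions given in full are those with the largest mean change. A region's FPKM is the geometric mean of its members in each library, averaged over libraries. Runs and adjacent pairs were compared with 10000 shuffles of gene order. Of the 1791 adjacent pairs 409 overlap, and values of overlapping features are uncertain because fragments can belong to both.

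The alternatives were deposited FPKM without rescaling, upper quartile and quantile normalization, pseudocounts of 0.1 and 10, no filter and a filter at a mean of 10 FPKM, leaving out each library in turn, the replicate number as a block, limma without the trend, with robust moderation and with library weights, camera with an estimated correlation, and fry (the last 2 planned for the gene lists and run on the blocks). Added after the data were seen were features of at least 300 bases with lengths in whole codons (in place of a planned restriction to protein-coding genes, since the tables name no gene types), limma voom on estimated fragments, a term for the 3 deeper libraries, the 5 shallower libraries alone (2 light and 3 dark), the 3 deeper ones alone (2 light and 1 dark, where the lone dark library is assumed to vary like the light ones), the comparison without the 2 libraries at the end of the second principal component, blocks shifted by 10 features, and a repeat of the principal components and of the comparison of same-numbered libraries over features of at least 300 bases.

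The test was tried on simulated data with the real means and spread of 1792 features. Of 50 features changed by each size, it recovered 58% at a log2 change of 0.25, 90% at 0.5, 98% at 1 and 100% at 2, and it called 6 of 1592 unchanged ones. The simulation drew noise independently for each feature and changed far fewer features than passed in the real data. In simulated gene orders 3 of 3 planted runs were found, and 2 of 100 shuffled orders gave p under 0.05. These last 2 only check the procedure, since the planted runs were clear by construction and shuffled orders were compared with shuffled orders.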

Results

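Gene expression was measured by stranded RNA sequencing in 8 cultures of Aurantimicrobium sp. strain MWH-Mo1, an actinobacterium named in the series title as one without phototrophy. The cultures fell into 2 groups of 4. One group was kept in constant light of about 30 to 40 µmol photons m-2 s-1 given by a compact fluorescent lamp of 13 W, and the other in constant darkness. The comparison asks which transcripts differed between cells of this bacterium grown with and without light, in a series whose title concerns faster growth in light. The values are FPKM (fragments scaled to the length of the gene and to the mapped total of the library) for 1792 features on a single sequence that the tables call mo1genome. The last base listed is 1747718. Of the feature lengths, 98.2% are multiples of 3, so lengths are given as coding length, with a median of 825 bases. The tables pair no gene name or product with their locus tags, so features are given by 1-based position on mo1genome and at most 4 by tag. The tables state no fragment totals. The confidence intervals listed beside the FPKM correspond to an estimated 1.08e+07 to 1.36e+07 fragments in genes per library, which can be too low because of overlapping features. The median feature had an interval of 4.59 to 4.83% on either side of its value.

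The light and dark libraries formed separate groups. Pearson's r across genes, which are not independent replicates, lay between 0.985 and 0.995 for libraries of the same group and between 0.958 and 0.978 for libraries of different groups. The first principal component carried 63.0% of the variance, and its scores ran from -11.2 to -7.10 in light and from 8.18 to 12.5 in darkness. Replicates differed by more than the listed intervals allow, so none was counted as a copy of another. The limma p-values of single features set their differences against the spread between these 4 and 4 cultures, and the labels do not say whether each culture had its own inoculum. Permutation p-values from shuffled gene orders take gene positions as units instead.

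Most genes differed between light and dark, and most of them by little. Of 1792 features, 577 rose in light and 563 fell, together 63.6% of those tested. The median log2 fold change was 0.33 among features that rose and -0.39 among those that fell, beside a median standard error of 0.062. Changes of at least 2-fold were fewer and leaned downwards, with 12 features higher and 44 lower in light. In 1077 features (60.1%) the 4 light libraries all lay above or all below the 4 dark ones, where chance gives 2.86%, and this held for 12 of the 12 rises and 42 of the 44 falls of at least 2-fold. Features counted here had an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment (1206 had an unadjusted p under 0.05). The number of at least 2-fold falls was 28 after quantile normalization, and that of rises was 6 in limma voom on fragments estimated from the intervals and 19 without light replicate 1 and dark replicate 4.

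**Figure D1:**
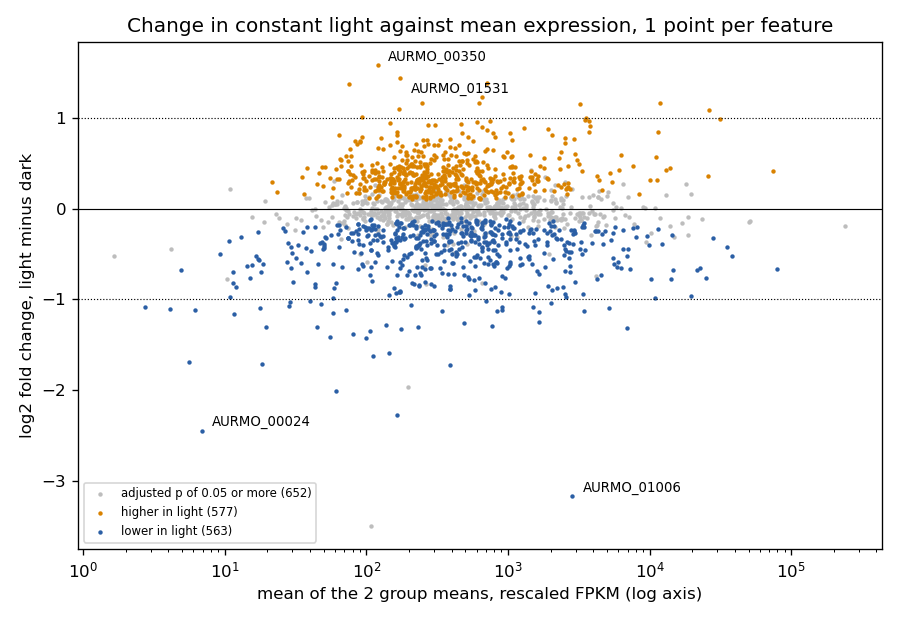
Log2 fold change (light minus dark, on log2 of rescaled FPKM + 1) against mean expression in FPKM on a log axis, with 1 point for each of 1792 features. Orange points (577) rose in light, blue points (563) fell and grey points had an adjusted p of 0.05 or more, and dotted lines mark 2-fold change, beyond which lie 12 rises and 44 falls past the threshold.

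The largest rise was in AURMO_00350 (bases 321716 to 322702), which had 181 ± 25.9 FPKM in light and 60.0 ± 6.73 in darkness (SD, n = 4 each), a log2 fold change of 1.57 with a standard error of 0.11 (limma adjusted p = 6.2e-06). AURMO_01531 (bases 1502333 to 1503601) had 254 ± 14.96 FPKM in light and 93.6 ± 6.01 in darkness (SD, n = 4 each), a log2 fold change of 1.43 with a standard error of 0.06 (limma adjusted p = 5.4e-07). With limma voom on estimated fragments the log2 fold changes of these 2 features were smaller, at 0.99 and 0.66, and still past the threshold. Both overlap a neighbouring feature by a few bases, so fragments at their ends could count for either and their estimated fragments can be too low. AURMO_00350 (987 bases) had an estimated 7200 fragments over 8 libraries. The feature at 1382224 to 1383300 (1077 bases, 54.2 FPKM in light and 168 in darkness), which overlaps none, had 13643. The voom values are therefore no sound measure of the size of these 2 changes. The 10 largest rises lay in 6 places. They included 3 features between bases 319364 and 322702, another 3 between 1500589 and 1504779, and single features at 177783 to 179489, 536393 to 537397, 838568 to 839752 and 1274730 to 1275707. Their log2 fold changes ran from 1.10 to 1.57.

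Among features past the threshold with all 4 light libraries below the 4 dark ones, the largest fall was in AURMO_01006 (bases 999489 to 1000966). The lowest log2 fold change of all 1792 features, -3.49, was in a feature that did not meet this rule. AURMO_01006 fell by a size that differed widely among dark cultures. Its FPKM was 260, 554, 300 and 523 in the light libraries and 981, 3895, 2892 and 13442 in the dark ones, a log2 fold change of -3.17 with a standard error of 0.67 (limma adjusted p = 0.0027). Without dark replicate 4 the dark mean was 2589 ± 1480 FPKM (SD, n = 3) and the log2 fold change -2.52 (limma adjusted p = 0.0022). The 3118-base feature before it (bases 995949 to 999066) had 2800 ± 338 FPKM in light and 5559 ± 4131 in darkness (SD, n = 4 each), and its difference did not pass (log2 fold change -0.74, limma adjusted p = 0.133). A feature of 120 bases at slightly lower coordinates (995700 to 995819) was also among the 10 largest falls by this rule, with a log2 fold change of -1.73. The tables name no gene types. The lengths of AURMO_01006 (1478 bases) and of the feature before it are not multiples of 3, unlike 98.2% of lengths. This argues against either being a whole reading frame. The 3 features have lengths of the kind found in bacterial rRNA operons, and rRNA was depleted before sequencing. The fall may therefore be in rRNA left by the depletion and not in a messenger RNA, which the values do not decide. AURMO_00024 (bases 19911 to 20138) was barely expressed. It had 1.36, 2.75, 0 and 1.14 FPKM in the light libraries and 5.45, 23.6, 15.5 and 5.41 in the dark ones, with a log2 fold change of -2.45 and a standard error of 0.53 (limma adjusted p = 0.0030) that rest on an estimated 39.5 fragments over all 8 libraries. Its log2 fold change was set largely by the processing, at -0.92 with a pseudocount of 10 FPKM, -1.43 after quantile normalization and -3.61 with a pseudocount of 0.1. In the 5 less deeply sequenced libraries alone it did not pass (-1.76, limma adjusted p = 0.0733, over a range of 0.0017 to 0.0733 among 21 alternatives). Another large fall lay at 85376 to 87397, with 50.4 ± 13.2 FPKM in light (SD, n = 4) and 168, 580, 175 and 195 in the dark libraries, where the log2 fold change was -2.27, and -1.84 without dark replicate 2, which left a dark mean of 179 ± 13.99 (SD, n = 3). The feature at 1409446 to 1409736 had 23.3 ± 3.78 FPKM in light and 99.1 ± 31.5 in darkness (SD, n = 4 each).

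Features that rose stood together in stretches of the genome. There were 17 runs of at least 6 neighbouring features that all rose, holding 130 features. The strongest on average covered bases 1498031 to 1504779, where 6 features had a geometric mean of 307 ± 10.2 FPKM in light and 156 ± 10.6 in darkness (SD, n = 4 each), a mean log2 fold change of 0.98. The 9 features from 316510 to 323460, the stretch that holds AURMO_00350, went from 440 ± 39.3 FPKM in darkness to 771 ± 69.8 in light (mean log2 fold change 0.81). The 7 features from 587913 to 596870 went from 1003 ± 44.2 to 1617 ± 34.6 (0.69). The first of these, at 587913 to 589193, was the most strongly expressed of the 12 features that rose at least 2-fold, with 35588 ± 1315 FPKM in light and 16839 ± 2193 in darkness and a log2 fold change of 1.09. The longest run held 22 features from 1267433 to 1289095, at 120 ± 9.72 FPKM in darkness and 188 ± 9.46 in light (0.65). A further 6 features from 1692797 to 1697593 went from 232 ± 8.90 to 358 ± 29.6 (0.62).

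Falling features formed 8 runs with 67 members. The deepest covered bases 1368103 to 1385082 and held 13 features, 10 of which fell at least 2-fold. The geometric mean of the 13 features went from 140 ± 8.01 FPKM in darkness to 60.6 ± 3.58 in light (SD, n = 4 each), a mean log2 fold change of -1.21. Members ranged from -1.62 to -0.57. Another 7 features from 1467080 to 1473650 stood at 2430 ± 94.2 FPKM in darkness and 1343 ± 56.1 in light (-0.86), and the most strongly expressed of them, at 1469402 to 1469593, at 18007 ± 1650 and 10501 ± 669. The 11 features from 1581651 to 1592789 fell from 375 ± 20.4 to 229 ± 2.42 FPKM (-0.71), the 7 from 655920 to 662211 from 1289 ± 99.02 to 836 ± 25.0 (-0.62) and the 10 from 1568715 to 1577249 from 1064 ± 30.9 to 768 ± 13.2 (-0.47).

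**Figure D2:**
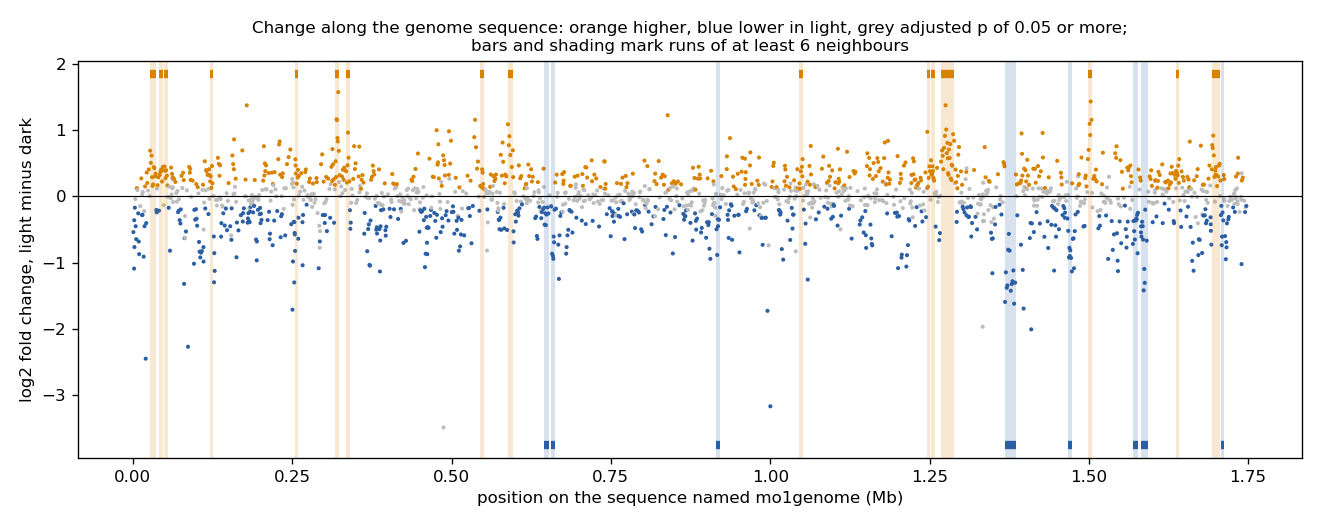
Log2 fold change (light minus dark) of each of 1792 features against its position on mo1genome in Mb, with orange for features that rose, blue for those that fell and grey for an adjusted p of 0.05 or more. Bars and shading mark the 17 rising and 8 falling runs of at least 6 neighbours, of which the run of 13 features from 1368103 to 1385082 reaches the lowest mean, -1.21.

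**Figure D3:**
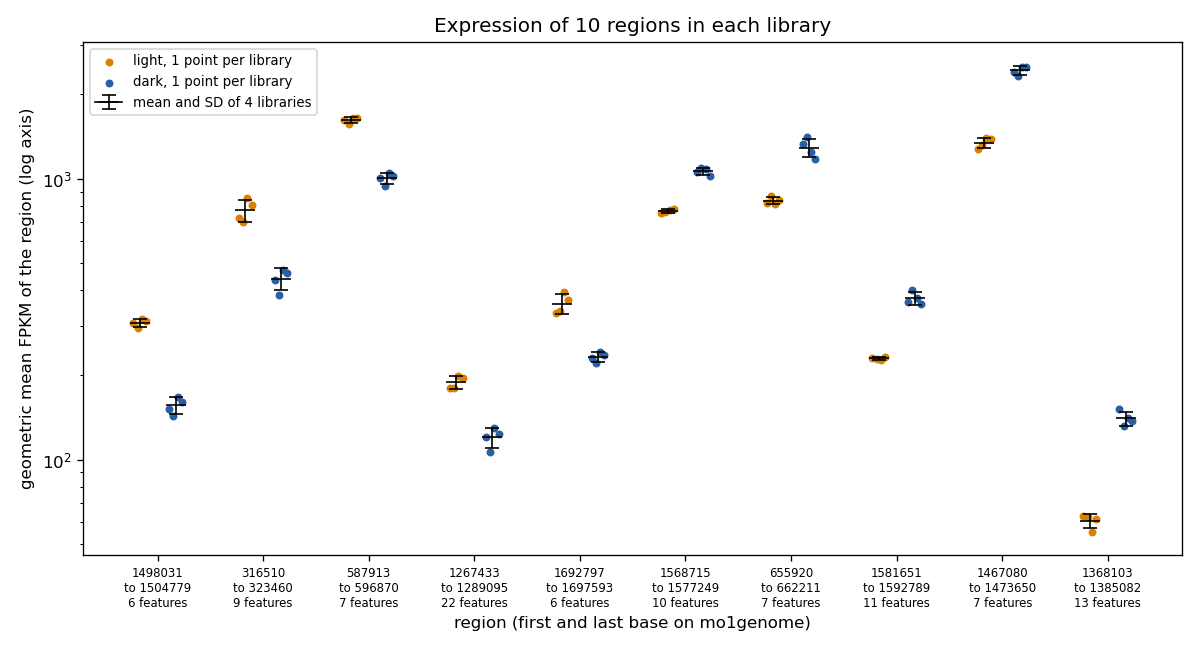
Geometric mean FPKM (log axis) of 10 regions in each library, light in orange and dark in blue, with the mean and SD of 4 libraries as black lines. The light libraries of the region from 1498031 to 1504779 centre on 307 FPKM against 156 in darkness, and those of the region from 1368103 to 1385082 on 60.6 against 140.

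Neighbours changed together more often than gene order alone gives. Among 1791 pairs of adjacent features, 566 both rose or both fell, against a mean of 362 and a highest value of 416 in 10000 shuffled gene orders, and 194 changed in opposite ways, against a mean of 363 and a lowest value of 311. The 25 runs of at least 6 compare with a mean of 2.49 and a highest value of 10 in shuffled orders. Each of these had a one-sided permutation p of 0.0001, the smallest that 10000 shuffles can give. There were 16 runs without light replicate 4, 10 with limma voom and 9 in the 5 less deeply sequenced libraries. Pairs that changed the same way numbered 334 in these 5 libraries, where 796 features passed the threshold. Fewer features past the threshold leave fewer such pairs and runs in shuffled orders too. Gene order was not shuffled under these alternatives, so the lower counts do not show that neighbours changed together less.

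Divided into 90 consecutive blocks, 89 of 20 features and the last of 12, the sequence had 4 blocks that were higher and 6 that were lower in light by limma's camera test with a preset correlation of 0.01. The lowest adjusted p was 0.0010, for bases 1264643 to 1284231, where 17 of 20 features rose and 2 fell, followed by 0.0016 for bases 1360338 to 1385082, where 14 fell and 3 rose. No block passed with an estimated correlation (lowest adjusted p = 0.644).

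Rises and falls occurred at every level of expression and length. In 5 classes of increasing mean expression, 94 features rose and 136 fell in the lowest, then 157 and 95, 128 and 88, 119 and 117, and in the highest 79 and 127. In the lowest class 23 of the falls and 3 of the rises were at least 2-fold. In 5 classes of increasing length, 5 features rose and 14 fell among those shorter than 150 bases, then 42 and 45, 120 and 126, 243 and 244, and 167 and 134 among the longest. Differences between classes were not tested, and the balance moves with scaling, since 56.4% of the features past the threshold were higher without rescaling against 50.6% with it. The median expression was 436 FPKM for features that rose at least 2-fold and 124 for those that fell as much.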

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

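Chosen only after the results were seen were the principal components over longer features and the test on RNA left by rRNA depletion.

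Among 40 sets of 4 library values examined, 3 held a library far from the others of its group, where chance gives about 2. On the first principal component dark replicate 2 stood at 12.5 and the nearest dark library at 8.58, a gap of 0.908 of the dark range. On the second component light replicate 1 stood at 6.13 and the nearest light library at -2.10 (0.909 of the range), and dark replicate 4 at 7.79 with the nearest dark library at -2.10 (0.956). A single feature of 73 bases (1545784 to 1545856) held 69.5% of the squared loading of the second component, and it was listed at 0 in these 2 libraries and at 150 to 307 FPKM in the other 6. Over the 1592 features of at least 300 bases the gap of light replicate 1 on the second component was 0.451 of the light range, and dark replicate 4 stood at -3.70, near dark replicate 3 at -2.90. The widest dark gap there was that of dark replicate 2 (4.91, with the nearest at 0.37), at 0.527 of the range, and its gap on the first component over the same features was 0.879.

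The real division of the libraries stood above all others in the number of genes past the threshold and in those changed at least 2-fold. In 1 of 35 splits of the 8 libraries into 4 and 4, the real one, 1140 genes passed, and the highest other split gave 1. For changes of at least 2-fold the real split gave 56 and the highest other 1, so again 1 of 35 splits was as large. For blocks of 20 neighbouring features chance cannot be excluded: the real split gave 10, the highest other 13, and 6 of 35 splits gave as many.

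AURMO_01006 had the largest fall among features past the threshold whose light libraries all lay below the dark ones. Its values spread widely between dark libraries. The rescaling applied here changed this fall little: the log2 fold change was -3.13 (standard error 0.66, limma adjusted p = 0.0025) with the deposited FPKM not rescaled. Its factors of 0.965 to 1.02 were too close to 1 to bring the value near 0. The deposited FPKM are already scaled to the mapped total, so scaling in general was not tested. The feature may itself be rRNA, since it and the features of 3118 and 120 bases before it have lengths of the kind found in bacterial rRNA operons, and abundant RNA left by the rRNA depletion to a different extent in each library is then a candidate explanation. The values do not decide this: the spread of the feature within groups lay at percentile 100 among the 100 genes nearest in mean expression (SD 1.17 on the log2 scale, against a highest of 0.489), which restates the spread that prompted the test and would follow from any other source of variation. The feature before it was also highest in dark replicate 4, and together they took 1.11 to 1.42% of the estimated fragments in light libraries and 1.16 to 6.95% in dark ones. These shares may be too high, since estimates for overlapping features can be too low. A response to light stays open as well.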

How the results depend on the processing

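Chosen after the data were seen were the counts of runs, adjacent pairs and blocks, the fits on whole-codon features, by voom, by depth and without 2 libraries, the shifted blocks, and the check of same-numbered libraries over longer features. The number of genes past the threshold (1140) stayed within 1.5 times under 23 alternatives, from 796 in the 5 shallower libraries to 1219 with library weights. Without rescaling it was 1134, of which 56.4% were higher in light against 50.6%, and after quantile normalization 1114, with 4 genes called in the opposite direction. Not counted among these are lifting the filter, which had removed no gene, and the 3 deeper libraries, whose lone dark library is assumed to vary like the 2 light ones, so that their values say nothing about stability. The planned restriction to protein-coding genes and the gene lists were not run.

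Leaving out each library in turn gave 1032 to 1153 genes, 523 to 590 higher and 509 to 563 lower, 11 to 18 and 37 to 49 of them at least 2-fold, 485 to 565 adjacent pairs, 16 to 23 runs (16 without light replicate 4, against 25), and 3 to 4 higher and 4 to 6 lower blocks. At least 2-fold falls (44) became 28 with quantile normalization. At least 2-fold rises (12) became 6 with voom and 19 without light replicate 1 and dark replicate 4. Runs became 10 with voom, 9 in the 5 shallower and 13 in the 3 deeper libraries, and adjacent pairs changed the same way (566) became 334 and 370 in these subsets, which hold fewer samples (2 light and 3 dark, and 2 light and 1 dark). Lower blocks (6) became 3 over whole-codon features and 2 in the 3 deeper libraries. With an estimated correlation 0 blocks were higher and 0 lower, and with fry, which tests each block by itself, 27 and 28. For the other changes the cause was not tested.

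With the replicate number as a block 1169 genes passed, and 1115 of the 1140 were among them. Over all features the deviations of same-numbered libraries from their group means correlated at -0.05, 0.17, 0.25 and 0.04, so the numbers were not taken to pair the cultures. That reading depends on the features used: over those of at least 300 bases the correlations were 0.23, 0.32, 0.38 and 0.24. In neither case did every light library correlate best with its own number (2 of 4 did).

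AURMO_00350 and AURMO_01531 passed under these 23 alternatives and AURMO_01006 under the 22 that tested it, but their size moved: log2 fold changes ran from 0.99 to 1.65, from 0.66 to 1.48 (both lowest with voom) and from -3.78 to -2.33. The voom values of the first 2 rest on estimated fragments that can be too low, because both features overlap a neighbour. AURMO_00024, at an estimated 39.5 fragments in all, ran from -3.61 with a pseudocount of 0.1 to -0.92 with 10, and passed in 20 of 21.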

Other observations

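The test on distance from the sequence start and the counts of falls and rises outside runs were chosen only after the results were seen.

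Genes that lie close together changed most alike. The log2 fold changes of overlapping neighbours (409 pairs) correlated at 0.656, of those 0 to 20 bases apart at 0.548, of those 21 to 100 apart at 0.266, of those farther apart, up to 300 bases, at 0.173 and of the 36 pairs over 300 apart at 0.051 (Pearson's r across gene pairs, which are not independent replicates). Among pairs with both members past the threshold, 86.3% of overlapping ones went the same way, against 59.5% of those over 100 and up to 300 bases apart. The hypothesis that close genes change more alike was borne out in these data: r was 0.604 for 852 pairs that overlap or lie within 20 bases and 0.149 for 323 pairs over 100 apart, a difference of 0.455 where shuffled gaps reached 0.271.

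Fragments shared between neighbours may add to this likeness, and whether they are its whole cause stays undecided. Features on either side of a gene of at least 1000 bases, longer than any selected fragment, correlated at 0.214 over 659 such cases (highest of shuffled orders 0.143). No fragment spans such a gene, but fragments at either end of it can also count for the feature beside that end. Sharing alone could thus make both flanking features follow the gene between them. A broad trend along the genome is argued against. Neighbours correlated at 0.361 after a running median over 50 genes on each side was taken off (highest of shuffled orders 0.096). Transcription of adjacent genes in shared units is a hypothesis that stays open. The tables used here list no strand or transcript ends with which to test it.

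Falls of at least 2-fold outnumbered rises by 44 to 12. The rescaling applied here changed these counts little, with 42 falls and 15 rises in the deposited FPKM, a ratio of 2.8. Its factors of 0.965 to 1.02 were too close to 1 to bring falls and rises near each other. Since the deposited FPKM are already scaled to the mapped total, scaling in general was not tested as a cause. Whether short or weakly expressed features are the cause stays open. At least 2-fold falls and rises numbered 23 and 3 in the lowest of 5 expression classes. In the classes above it they numbered 5 and 3, 3 and 0, 5 and 3, and 8 and 3. Among 1513 features of at least 300 bases and 50 FPKM there were 22 falls and 11 rises, a ratio of 2. Of these falls 9 lie in the run from 1368103 to 1385082, and outside it 13 falls stand against 11 rises. Leaving out the members of all 25 runs, rising ones included, gives 11 falls and 3 rises, so the balance depends on how neighbours that change together are counted. The excess was smaller after quantile normalization, which reshapes each library's distribution, at 28 falls and 16 rises, and the cause of that drop was not tested. A response to light stays open as an untested explanation.

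A hypothesis that faster growth in light raised genes near the start of the listed sequence through gene dosage was not borne out. Spearman's rho between log2 fold change and circular distance from base 1 was -0.012, inside the central 95% of 1791 circular shifts of gene order (-0.030 to 0.032, permutation p = 0.834). The test holds only if the listed sequence is a circle that begins near the origin of replication, which the tables do not say.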
